A study of Mus musculus with 8 samples.

How the data were processed

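Gene expression was measured on 8 mouse arrays of 1 colour (Cy3). RNA came from mouse embryonic fibroblasts (MEFs) of 2 lines, one wild type (WT) and one without Keap1 (Keap1 null), both carrying the letters TR in the labels, which do not spell them out. Each line was profiled from culture dishes and from tumours that the injected cells formed in nude mice (allografts), with 2 arrays per group. Per the labels, 10000000 WT cells or 3000000 Keap1 null cells were injected, tumours were taken at 100 to 150 mm3, and each labelling started from 500 ng of RNA. Whether replicates 1 and 2 are separate cultures, animals or repeated hybridisations is not stated. Single-gene p-values measure spread between arrays, and the rest compare genes or probes.

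The deposited scanner files hold intensities written by Agilent Feature Extraction 10.7.3.1, per the file headers. The processed signal used here is an intensity from which the scanner software had subtracted the background and a spatial trend, with no scaling between arrays, per the file headers. The deposited value table of the series holds the same intensities, rounded: no value differed from the processed signal of its spot by more than 0.5%, so its scale is linear and it carries no centring or scaling.

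Intensities were scaled with R 4.3.3 and tested with limma 3.58.1. The log2 of the processed signal minus the 75th percentile of its array was used, control spots were excluded, spots marked as outliers were left out, and repeated spots of a probe were averaged. A probe was tested when it was well above background on both arrays of at least 1 group, which held for 30355 of the 41174 probes. Accessions of the array design, without version numbers, were matched to the RefSeq gene table of assembly GRCm38.p6, used for names only because the headers name the older build mm9. This gave 26690 probes a gene symbol, for 18217 symbols, and left 14484 probes without one. A gene was represented by its tested probe with the highest mean over all arrays, giving 22919 targets, of which 14855 have a symbol and 8064 do not. Of 5725 targets with several tested probes, 15, 38, 292, 160 and 47 had probes called in opposite directions in the 5 comparisons, in the order in which they are described.

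One limma fit of 4 group means over all 8 arrays, with 4 residual degrees of freedom and 1.83 prior degrees of freedom, gave 5 comparisons: Keap1 null against WT in dish, the same in allograft, allograft against dish in WT, the same in Keap1 null, and their interaction. A target was called at a Benjamini-Hochberg adjusted p below 0.05. An exact permutation of 2 arrays against 2 cannot go below 0.33, so no such test was made of single genes. Fold changes are ratios of geometric means of scaled intensity. Where a gene was not well above background on any array of the dim group, the fold is a bound, written as at least N-fold: the bright group's mean was set against the higher, per array, of the dim probe's own signal and the lowest signal of any probe well above background. The number of arrays limits the precision of every value. Shared calls between 2 comparisons were counted per direction and set against the overlap of independent lists, with a one-sided Fisher exact test. The comparisons set side by side share no arrays, but they share the fit's estimate of the spread of each target. Their calls are therefore not independent, and a shared spread can raise the overlap in any direction.

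Gene lists were tested with limma's camera with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 26 lists. These hold NRF2 targets, pentose phosphate and NADPH genes, ATF4 targets with serine synthesis, hypoxia response, cell cycle, cholesterol synthesis, extracellular matrix, contractile and myofibroblast genes, matrix proteases, inflammatory cytokines and chemokines, interferon response, immediate early genes, p53 targets, heat shock and protein folding, and Hox and limb or trunk position genes. The others are markers of macrophages, MHC class II cells, neutrophils, lymphocytes (B, T and NK cells), endothelium, red cells, skeletal muscle, adipocytes, keratinocytes, pericytes and fibroblasts, and sex. The correlation estimated from the data was an alternative, and with it only the NRF2 list in dish stayed called. With a block for the replicate number added to it, 0 lists stayed called. Genes named in the text follow a rule: Keap1 and Nfe2l2 always, the 5 largest rises and 5 largest falls of each comparison among called genes with a symbol, well above background on both arrays of the brighter group and without overlap between the groups' arrays, and up to 4 called members of each list with the largest change. For the interaction, the largest rises and falls were taken among all called genes. Where no member of a list was called, up to 2 of its brightest members could be named. The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

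The files show that all arrays of replicate 1 shared slide 1 and all arrays of replicate 2 shared slide 2, each slide with 1 scan, so replicate number, slide and scan are the same division, and the position on the slide follows the group. Same-numbered arrays deviated together: over the 6 pairs of groups, the correlation of replicate differences across targets ranged from 0.247 to 0.429. The numbers therefore pair the arrays through the slide, and a fit with this replicate block is an alternative. Among called targets, 4842 of 4843, 9571 of 9574, 15594 of 15599, 14871 of 14874 and 7528 of 7529 had the same sign on both slides. A call needs a small spread between these same arrays, so this agreement was nearly fixed by the calling. Over all targets, called or not, the fold changes of the 2 slides correlated at r = 0.835, 0.909, 0.97, 0.961 and 0.87. The median absolute log2 difference between the 2 arrays of a group was 0.131 to 0.191, against a median SD of 0.0416 to 0.066 for repeated spots of a probe within an array.

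The steps were tested on simulated data with 22897 targets, of which 50 were changed at each fold size. In the dish comparison of genotypes, 8%, 44%, 72% and 94% of targets changed 1.5, 2, 4 and 8-fold were called with the right sign. In the same order, recovery was 16%, 36%, 74% and 92% for genotype in allograft, 10%, 36%, 78% and 90% for growth in WT, 20%, 52%, 80% and 90% for growth in Keap1 null, and 0%, 16%, 62% and 80% for the interaction. Unchanged targets called numbered 13, 3, 2, 9 and 9. A raised NRF2 list was called in each simulation, and 1 of the 25 other lists, the pentose phosphate list, which shares members with it, was called too. The simulated noise was independent between targets and arrays, without a slide effect or correlation between genes. Far fewer targets were changed than were called in the data, which makes the adjusted threshold stricter. These values therefore check the steps and do not give the recovery or the false calls in the data.

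Alternatives were normexp with an offset of 50, quantile normalization, the median of each array, the unscaled value table, no filter on dim probes, a filter of well above background on all 8 arrays, the mean of a gene's probes, the replicate block, a fit of only the arrays compared, an intensity trend with robust variances, a 2-fold minimum, an adjusted p below 0.01, an estimated correlation and fry for the lists, and leaving out each array. The planned normexp on mean signals was not run, because the scanner files hold median signals; normexp on medians was chosen after seeing the data, as were a fit of symbol-bearing targets alone and the replicate block with an estimated correlation. Leaving out an array leaves its group with 1, whose spread is assumed to be that of the other groups.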

Results

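Expression was compared between WT and Keap1 null MEFs, each grown in dishes and as allografts in nude mice, on 2 arrays per group. Keap1 is the adaptor protein that marks the transcription factor NRF2, encoded by Nfe2l2, for degradation, and NRF2 drives genes of glutathione metabolism, detoxification and NADPH supply. Between 60.6% and 64.5% of probes were well above background on the dish arrays, and between 69.8% and 74.7% on the allograft arrays. The median processed intensity was 44.8 to 61.9 on dish arrays and 106.1 to 137.4 on allograft arrays, the 75th percentile lay between 1084 and 1546 on all 8, and no spot was saturated. The first principal component held 74% of the variance and separated dish from allograft arrays, and the second held 15.9% and separated the lines, by more in allografts than in dishes.

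The targeted gene was read first on every array. Relative to the 75th percentile of the array, log2 Keap1 was 3.32 and 2.99 in WT dishes, 2.37 and 2.22 in Keap1 null dishes, 2.85 and 2.46 in WT allografts, and 1.00 and 0.92 in Keap1 null allografts. Keap1 was thus 1.82-fold lower in Keap1 null than in WT dishes (log2 fold change -0.86 ± 0.17 SE, limma adjusted p = 0.0197) and 3.23-fold lower in the allografts (-1.69 ± 0.17, adjusted p = 0.000722), and it stayed well above background on all arrays. Whether the probe lies inside the deleted part of the gene is not recorded, and a probe outside it checks nothing about the labels. The dish call for Keap1 ended in the unscaled table (adjusted p = 0.0796) and without Keap1 null dish array 1 (0.078), Keap1 null dish array 2 (0.112) or WT dish array 1 (0.0952). Nfe2l2 itself did not differ in dishes (log2 fold change 0.07 ± 0.10, adjusted p = 0.743) and was 1.52-fold higher in Keap1 null allografts (0.60 ± 0.10, adjusted p = 0.00529; 0.239 in the unscaled table).

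**Figure D1:**
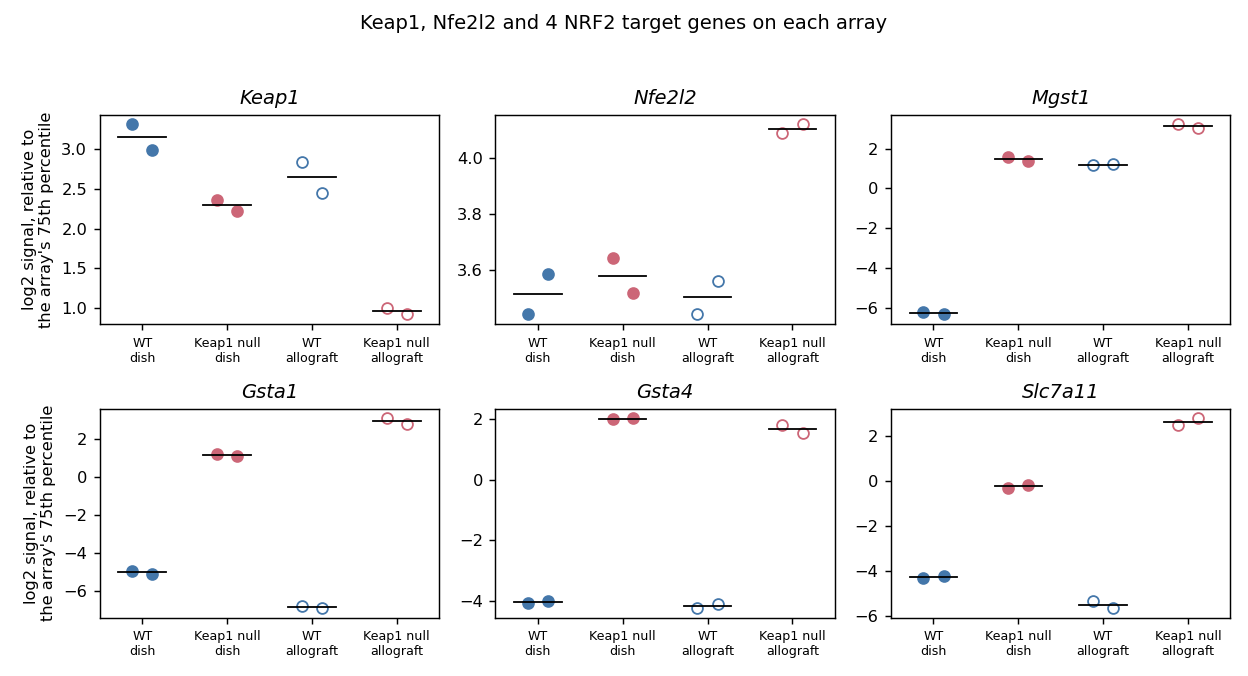
Log2 signal relative to the 75th percentile of each array (vertical axis) for Keap1, Nfe2l2 and 4 NRF2 target genes in the 4 groups; each point is an array, filled for dish and open for allograft, and the line is the mean of the group. Keap1 was lower on all Keap1 null arrays than on WT arrays of the same growth condition, and Mgst1, Gsta1, Gsta4 and Slc7a11 were higher.

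The first comparison asks what loss of Keap1 goes with in culture. In Keap1 null dishes, detoxification genes known to depend on NRF2 rose together. Mgst1, a membrane-bound glutathione transferase, was 214-fold higher (log2 fold change 7.74 ± 0.12 SE, adjusted p = 2.09e-05). The glutathione transferases Gsta1 and Gsta4 were 71.9-fold and 66.9-fold higher, and Gsta2 was 114-fold higher, though well above background on 1 of 2 WT arrays. Of 45 measured NRF2 targets, 32 rose and 2 fell (37 and 2 adjusted over the list alone), with a median log2 fold change of 0.86 (camera adjusted p = 6.6e-18, and adjusted p = 0.044 with an estimated correlation). With the replicate block and the estimated correlation together the call ended (camera adjusted p = 0.17). The median was 0.78 on slide 1 and 0.95 on slide 2.

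Genes of amino acid supply driven by ATF4 moved the other way. Of 23 ATF4 and serine synthesis genes, 16 fell and 2 rose (19 and 2 adjusted over the list alone). ATF4 targets had a median of -0.67 (camera adjusted p = 3.3e-07, and adjusted p = 0.26 with an estimated correlation). Chac1, which degrades glutathione, was 4.37-fold lower, Trib3 was 3.3-fold lower, and Psph, which makes serine, was 2.56-fold lower. An exception was Slc7a11, the cystine importer, which NRF2 also drives and which was 16.2-fold higher (adjusted p = 6.02e-05). Interferon response genes were lower as well: 12 of 30 fell and 2 rose (13 and 2 over the list alone), among them Oasl1 (6.03-fold), Rsad2 (4.28-fold) and Ifit1 (4.21-fold). Interferon genes had a median of -0.46 (camera adjusted p = 7.9e-05, and adjusted p = 0.75 with an estimated correlation).

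The lines also differed in genes that mark fibroblast type and body position. Of 17 pericyte and fibroblast markers, 10 rose in Keap1 null dishes and none fell (10 and 1 adjusted over the list alone), such as Thy1 (8.42-fold), Pdgfra (7.56-fold) and Pdgfrb (4.98-fold). Pericyte and fibroblast markers had a median of 1.01 (camera adjusted p = 0.00011, and adjusted p = 0.26 with an estimated correlation). Of 28 Hox and limb or trunk genes, 17 rose and 5 fell (18 and 6 over the list alone). Hox and limb genes had a median of 0.92 (camera adjusted p = 9.8e-06, and adjusted p = 0.071 with an estimated correlation). Hoxd13, a gene of the most distal limb, was at least 162-fold higher, Hoxd8 at least 10.3-fold, and the hindlimb gene Pitx1 at least 19.2-fold. Extracellular matrix genes rose more often than they fell, 11 against 5 of 27 (12 and 5 over the list alone), with decorin (Dcn) 11-fold and Col3a1 7.36-fold higher. Matrix genes had a median of 0.26 (camera adjusted p = 0.041, and adjusted p = 0.75 with an estimated correlation, and 0.063 with the replicate block).

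Among the largest fitted changes, Amph was at least 146-fold, Fndc3c1 at least 170-fold and Asb4 at least 32.4-fold higher in Keap1 null dishes. Cyp3a13, a cytochrome P450, was at least 26.8-fold lower, Igsf5 was 26.8-fold lower, the cardiac transcription factor Tbx20 was 24.6-fold lower, Btn1a1 at least 5.33-fold and Clec5a at least 4.88-fold. The matrix protease Mmp3 was 47.5-fold higher and the chemokine Ccl4 was 21.4-fold lower, but neither list was called: 3 of 19 matrix proteases rose and 5 fell (the same over the list alone, median 0.00, adjusted p = 0.85), and 7 of 22 cytokines and chemokines rose and 5 fell (8 and 7 over the list alone, median 0.44, or 0.08 with dim genes at their bounds, adjusted p = 0.59).

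Smaller shifts passed the test in 3 more lists. Of 31 hypoxia genes 7 fell and 3 rose (the same over the list alone), with Ndrg1 2.54-fold lower and adrenomedullin (Adm) 3.44-fold higher. Their median was -0.27 (camera adjusted p = 0.035, adjusted p = 0.79 with an estimated correlation, and 0.063 with the replicate block). Cell cycle genes had a median of -0.20, with 3 of 30 called lower and 0 over the list alone (camera adjusted p = 0.026, and adjusted p = 0.32 with an estimated correlation). Of 21 heat shock and protein folding genes 4 fell (the same over the list alone), with Hspb1 2.36-fold lower. Their median was -0.20 as well (camera adjusted p = 0.026, and adjusted p = 0.65 with an estimated correlation). With quantile normalization none of these 3 was called (hypoxia 0.27, cell cycle 0.52 and heat shock 0.52, with medians of -0.13, -0.07 and -0.10), nor in the unscaled table (0.088, 0.19 and 0.10). These 3 calls and that of the matrix list also ended when 1 of 2 dish arrays was left out: hypoxia at 0.056 without Keap1 null dish array 2 and 0.19 without WT dish array 1, cell cycle at 0.056 and 0.12, heat shock at 0.056 and 0.11, and matrix at 0.15 without WT dish array 2 and 0.08 without Keap1 null dish array 1.

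Lists without a call in dishes included pentose phosphate and NADPH (4 of 13 rose and 2 fell, 5 and 3 over the list alone, median 0.22, adjusted p = 0.39), cholesterol synthesis (0 rose and 3 of 24 fell, the same over the list alone, median -0.18, adjusted p = 0.071) and p53 targets (6 rose and 2 of 20 fell, 7 and 3 over the list alone, median 0.08, adjusted p = 0.25). Immediate early genes (4 rose and 3 of 21 fell, 4 and 7 over the list alone, median 0.09, adjusted p = 0.85) and contractile genes (1 rose and 2 of 13 fell, the same over the list alone, median -0.19 with a mean of 0.11, adjusted p = 0.76) were not called either.

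Markers of host tissues, which a culture should lack, moved little in dishes. Macrophage markers had 1 of 24 higher and 4 lower (median -0.12, adjusted p = 0.59), with Mrc1 2.66-fold higher, MHC class II genes 1 of 10 lower (median -0.10, adjusted p = 0.62), neutrophil markers 1 of 13 lower (median -0.14, adjusted p = 0.64) and lymphocyte markers 1 of 20 higher and 2 lower (median -0.14, adjusted p = 0.62), with Klrd1 7.27-fold lower. Endothelial markers had 3 of 22 higher and 3 lower (median -0.11 with a mean of 0.07, adjusted p = 0.85), adipocyte markers 1 of 13 higher and 1 lower (median -0.20, or 0.00 at the bounds, adjusted p = 0.76), with Lpl 3.25-fold higher, and keratinocyte markers 2 of 14 higher (median -0.13 with a mean of 0.06, adjusted p = 0.83). Each of these counts was the same over the list alone. Skeletal muscle markers had 1 of 15 higher and 0 over the list alone (median 0.03, adjusted p = 0.77). None of 5 red cell and 4 sex-linked markers was called in either way (medians 0.20, or 0.00 at the bounds, and -0.14, adjusted p = 0.85 and 0.70).

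In all, 4843 of 22919 targets were called in dishes, 2602 higher and 2241 lower, and 1899 changed at least 2-fold. The balance depended on scaling: 53.7% of calls were higher, against 37.3% with the median of each array and 76.4% in the unscaled table. The median over all targets was -0.05, against -0.21 with the median of each array. Leaving out Keap1 null dish array 1 left 2310 calls. Genotype and cell line are the same division, with 1 line per genotype, so no difference between the lines can be assigned to Keap1 by this design.

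The second comparison asks what loss of Keap1 goes with in tumours, which also hold host cells. The NRF2 genes were again higher in Keap1 null cells, now with more members and a larger median, though not for each gene: Mgst1 was 3.8-fold higher, against 214-fold in dishes. Gsta1 was 875-fold higher (log2 fold change 9.77, adjusted p = 5.03e-06), Gsta2 at least 549-fold, Slc7a11 278-fold and Gsta4 58-fold. Of 45 NRF2 targets, 39 rose and 3 fell (the same over the list alone). NRF2 targets had a median of 1.68 (camera adjusted p = 1.1e-15, and adjusted p = 0.059 with an estimated correlation). Genes of the pentose phosphate pathway and NADPH supply rose too, 8 of 13 against 2 (10 and 2 over the list alone). Pentose phosphate genes had a median of 1.01 (camera adjusted p = 0.0052, and adjusted p = 0.14 with an estimated correlation). Among them were Pgd (3.71-fold), Taldo1 (2.76-fold) and the mitochondrial folate enzyme Mthfd2 (2.58-fold), while Prps1, which makes the precursor of nucleotides, was 2.86-fold lower.

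The transcripts of ATF4 and serine synthesis genes differed in the other direction than in dishes. In allografts, 18 of 23 ATF4 and serine synthesis genes rose and none fell (20 and 1 over the list alone), with Nupr1 5.34-fold, Chac1 4.81-fold and Psat1, a serine synthesis enzyme, 3.31-fold higher. ATF4 targets had a median of 1.01 (camera adjusted p = 9.6e-08, and adjusted p = 0.14 with an estimated correlation). Hypoxia genes rose, 19 of 31 against 3 (the same over the list alone), including Stc2 (23.3-fold), Bnip3 (3.37-fold) and Vegfa (2.94-fold). Hypoxia genes had a median of 0.59 (camera adjusted p = 0.00067, and adjusted p = 0.37 with an estimated correlation). Immediate early genes rose, 12 of 21 against 1 (13 and 1 over the list alone), led by the orphan receptors Nr4a1 (33-fold) and Nr4a2 (32.4-fold). Immediate early genes had a median of 0.76 (camera adjusted p = 0.00012, and adjusted p = 0.13 with an estimated correlation). Heat shock and protein folding genes rose, 11 of 21 against 1 (12 and 1 over the list alone), with Hsph1 3.11-fold and Hyou1 2.55-fold higher. Heat shock genes had a median of 0.42 (camera adjusted p = 0.009, and adjusted p = 0.32 with an estimated correlation). Their call ended with quantile normalization (0.093, median 0.22) and in the unscaled table (0.055, median 0.19). Cholesterol synthesis genes rose, 10 of 24 against 1 (11 and 1 over the list alone). Cholesterol genes had a median of 0.30 (camera adjusted p = 0.033, and adjusted p = 0.45 with an estimated correlation). The cholesterol call ended without Keap1 null allograft array 1 (0.18) or WT allograft array 2 (0.099), with quantile normalization (0.11, median 0.18), in the unscaled table (0.10, median 0.07), with normexp (0.098) and with no filter on dim probes (0.07).

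Interferon response and leukocyte genes were lower in Keap1 null tumours. All 30 measured interferon response genes fell (30 over the list alone), by a median of -2.79 (camera adjusted p = 1.1e-15, and adjusted p = 0.19 with an estimated correlation). Ifit3 was 23.4-fold, Ifit1 15.2-fold and Oas3 11.4-fold lower. Macrophage markers fell, 20 of 24 against 1 higher (22 and 2 over the list alone), including Adgre1, which encodes F4/80 (10.4-fold), Ccr2 (8.27-fold) and C1qb (7.61-fold). Macrophage markers had a median of -2.12 (camera adjusted p = 6.1e-08, and adjusted p = 0.14 with an estimated correlation). MHC class II genes fell, 8 of 10 against 1 (the same over the list alone), with H2-DMb1 10-fold and H2-Aa 6.33-fold lower, whereas Flt3, a dendritic cell gene of the list, was 5.88-fold higher. MHC class II genes had a median of -2.31 (camera adjusted p = 0.00067, and adjusted p = 0.14 with an estimated correlation). Lymphocyte markers fell, 15 of 20 (15 over the list alone); the named ones, Gzma (14.5-fold), Ncr1 (at least 9.29-fold) and Nkg7 (7.87-fold), mark NK and cytotoxic cells. Lymphocyte markers had a median of -2.08, or -1.22 with dim genes at their bounds (camera adjusted p = 1.3e-05, and adjusted p = 0.22 with an estimated correlation). Among probes well above background on all arrays the MHC class II call ended with its median kept (0.13, median -2.37), and the lymphocyte call ended with a median of -0.17 (0.18). Neutrophil markers did not follow: 6 of 13 rose and 3 fell (the same over the list alone, median 0.91, adjusted p = 0.22), with S100a8 4.27-fold higher. Of 22 endothelial markers 7 fell and none rose (4 over the list alone, median -0.36, adjusted p = 0.23). The Y-linked genes Ddx3y and Eif2s3y, not well above background on any dish array, were 2.19-fold and 2.04-fold lower in Keap1 null than in WT allografts. A second Ddx3y probe was lower without a call (log2 fold change -0.94, limma adjusted p = 0.0993). The sex-linked list was not called (2 of 4 fell, the same over the list alone, median -0.97, adjusted p = 0.20).

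Matrix, contractile and p53 genes were lower in the Keap1 null tumours as well. Of 27 extracellular matrix genes, 15 fell and 4 rose (16 and 4 over the list alone), with periostin (Postn) 12-fold lower and thrombospondin 2 (Thbs2) 6.09-fold higher. Matrix genes had a median of -0.76 (camera adjusted p = 0.01, and adjusted p = 0.36 with an estimated correlation). Of 13 contractile genes, 9 fell and 1 rose (the same over the list alone), such as Myl9 (8.24-fold) and Mylk (3.65-fold). Contractile genes had a median of -0.97 (camera adjusted p = 0.0036, and adjusted p = 0.15 with an estimated correlation). Of 20 p53 targets, 15 fell and 1 rose (the same over the list alone), with Eda2r 6.96-fold, the death receptor Fas 5.59-fold and Ccng1 3.84-fold lower. p53 targets had a median of -0.77 (camera adjusted p = 2.7e-05, and adjusted p = 0.14 with an estimated correlation). Of 15 skeletal muscle markers 4 rose and none fell (the same over the list alone), with Eno3 7.17-fold higher. Muscle markers had a median of 1.55 (camera adjusted p = 0.018, and adjusted p = 0.54 with an estimated correlation). The muscle call ended without WT allograft array 2 (0.18) and Keap1 null allograft array 1 (0.17).

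**Figure D2:**
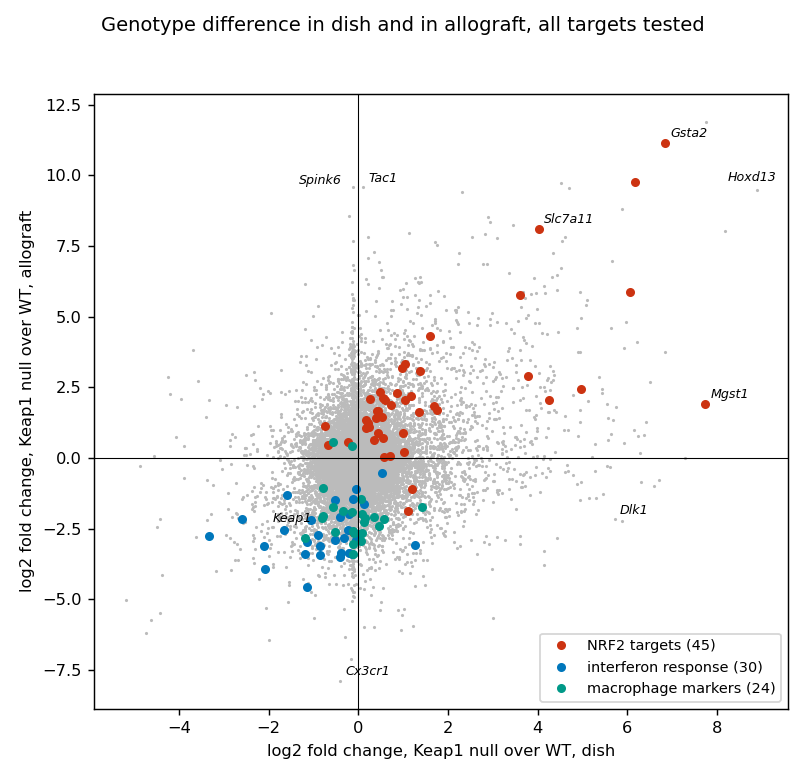
Log2 fold change of Keap1 null over WT in dish (horizontal) and in allograft (vertical) for all 22919 targets, with NRF2 targets, interferon response genes and macrophage markers coloured and 9 genes named. NRF2 targets lay mostly at upper right, and all 30 interferon genes lay below 0 on the vertical axis.

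Among the largest fitted differences were also Fndc3c1 (at least 1330-fold higher in Keap1 null allografts), the protease inhibitor gene Spink6 (at least 157-fold higher) and Tac1, which encodes substance P (763-fold higher). On the other side, the fractalkine receptor Cx3cr1 was at least 97.0-fold lower, Rflna at least 70.4-fold, Fam167a at least 31.4-fold, the keratin Krt7 79.4-fold and Igsf5 72.5-fold. Cytokines went both ways (7 of 22 rose and 13 fell, 7 and 14 over the list alone, median -0.92, adjusted p = 0.13): Ptgs2, which makes prostaglandins, was 85.2-fold and Il11 83.8-fold higher, while Cxcl12 and Ccl5 were each 13.4-fold lower. Matrix proteases went both ways too (8 of 19 rose and 5 fell, 9 and 5 over the list alone, median 0.16, adjusted p = 0.25), with Adamts1 8.25-fold higher and Mmp12 11.9-fold lower. Hox and limb genes split evenly, 13 of 28 higher and 11 lower (the same over the list alone, median -0.02 with a mean of 0.41, adjusted p = 0.80): Hoxd13 was 713-fold higher, though well above background on 1 of 2 WT arrays, and Hoxb8 was at least 10.1-fold lower. Not called were cell cycle (7 of 30 rose and none fell, 6 over the list alone, median 0.12, adjusted p = 0.15), pericyte and fibroblast (5 of 17 rose and 7 fell, the same over the list alone, median -0.12, adjusted p = 0.48), red cell (1 of 5 rose, the same over the list alone, median 0.65, adjusted p = 0.25), adipocyte (2 of 13 rose, the same over the list alone, median 0.56, adjusted p = 0.30) and keratinocyte markers (2 of 14 rose and 2 fell, the same over the list alone, median 0.88, adjusted p = 0.37). The adipocyte list was called without WT allograft array 1 (0.00068), and the keratinocyte list without Keap1 null allograft array 2 (0.00074).

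In the allograft comparison 9574 targets were called, 4688 higher and 4886 lower, and 4545 changed at least 2-fold. The share called higher was 49%, against 30.5% in the unscaled table, and the median over all targets was 0.00, against -0.22. Of the calls, 1093 were higher and 904 lower in both dishes and allografts, where independent lists would share 532 and 478. Odds ratios were 3.37 and 2.83 (one-sided Fisher exact p = 3.16e-158 and 1.29e-103, over targets treated as independent). Another 735 were higher in dishes and lower in allografts and 448 the reverse, for which no expected overlap was computed. Because both comparisons share the spread of each target, the overlap does not by itself measure agreement of the genotype effects. Across all targets, which are not independent replicates, the 2 sets of fold changes correlated at r = 0.254. The shared calls dropped to 1074 in total from 1997 without Keap1 null dish array 1. The number of injected cells differed between the genotypes, so it cannot be separated from genotype.

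The next comparisons ask, for WT and then for Keap1 null, how each line differs between allograft and dish. In both, many of the largest fitted rises were in genes of myeloid cells. In WT, the lysozyme gene Lyz1 was at least 4480-fold higher, the lysosomal protease gene Ctss at least 5530-fold, Pf4 at least 1760-fold, Pirb at least 1520-fold and the complement gene C1qc at least 1760-fold. In Keap1 null the same genes were at least 997-fold (Lyz1), 1440-fold (Ctss), 1640-fold (Pf4), 643-fold (Pirb) and 300-fold (C1qc) higher, and the pericyte channel gene Kcnj8 was at least 563-fold higher. All 24 macrophage markers rose in both lines (24 over the list alone in each), by a median of 10.04 in WT and 8.13 in Keap1 null, or 8.51 and 6.46 with dim genes at their bounds (camera adjusted p = 5.9e-12 and 2.1e-11, and adjusted p = 0.10 and 0.087 with an estimated correlation).

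Other host tissues appeared with them. Endothelial markers rose, 21 of 22 in each line (the same over the list alone), such as Emcn, at least 399-fold in WT and 285-fold in Keap1 null. Endothelial markers had medians of 5.80 and 5.36, or 5.44 and 4.25 at the bounds (camera adjusted p = 8.5e-09 and 3e-09, and adjusted p = 0.10 and 0.087 with an estimated correlation). MHC class II genes rose, 9 of 10 in each line (the same over the list alone), such as H2-Ab1, at least 567-fold higher in WT. MHC class II genes had medians of 6.23 and 3.93, or 4.04 and 2.88 at the bounds (camera adjusted p = 7.7e-05 and 0.00038, and adjusted p = 0.10 and 0.087 with an estimated correlation). Neutrophil markers rose, 9 of 13 in WT and 13 of 13 in Keap1 null (the same over the list alone), such as S100a9, at least 143-fold and 287-fold. Neutrophil markers had medians of 3.48 and 3.74, or 1.23 and 1.73 at the bounds (camera adjusted p = 0.0088 and 0.00019, and adjusted p = 0.12 and 0.087 with an estimated correlation). Lymphocyte markers rose in WT, 15 of 20 (15 over the list alone), with Prf1 at least 62.8-fold higher. Lymphocyte markers had a median of 2.25, or 1.31 at the bounds (camera adjusted p = 0.00048, and adjusted p = 0.23 with an estimated correlation). Among probes well above background on all arrays that call ended (0.25, median 0.05). In Keap1 null 9 rose and 1 fell (the same over the list alone), and the list was not called (median 0.95, or 0.00 at the bounds, adjusted p = 0.079), but it was called with the median of each array (0.016), with symbols only (0.0078), with no filter on dim probes (0.043) and without Keap1 null allograft array 1 (0.012). The Y-linked genes Eif2s3y and Ddx3y were at least 59.1-fold and 48.1-fold higher in WT allografts and at least 31-fold and 23.5-fold higher in Keap1 null allografts. The sex-linked list rose with them, 4 of 4 in each line (the same over the list alone). Its X-linked member Xist, which female cells express, was already 2.44 to 2.61 on the dish arrays and was 1.69-fold and 1.85-fold higher in the allografts of WT and Keap1 null. Sex-linked markers had medians of 5.07 and 4.49, or 3.98 and 3.38 at the bounds (camera adjusted p = 0.016 and 0.017, and adjusted p = 0.12 and 0.17 with an estimated correlation).

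Markers of muscle, fat, blood and skin were less even. Skeletal muscle markers rose in Keap1 null, 13 of 15 (14 over the list alone), with the myosin gene Myh2 at least 402-fold higher, at 3.38 and 0.50 on the Keap1 null allograft arrays. Muscle markers had a median of 3.03, or 2.77 at the bounds (camera adjusted p = 0.0047, and adjusted p = 0.47 with an estimated correlation). In WT 8 rose and 1 fell (the same over the list alone, median 2.52, or 1.16 at the bounds, adjusted p = 0.13), and the list was called with the median of each array (0.016), with symbols only (0.027), with no filter on dim probes (0.034) and without WT allograft array 2 (0.029). Adipocyte markers had 8 of 13 higher and 1 lower in each line (the same over the list alone, medians 2.63 and 2.67, adjusted p = 0.11 and 0.065), with Cd36 at least 30.1-fold and 34.1-fold higher. Red cell markers had 3 of 5 higher in each (in WT 3 and 1 lower over the list alone, in Keap1 null 3, medians 5.92 and 6.13, or 4.01 and 4.76 at the bounds, adjusted p = 0.13 and 0.054), with the haemoglobin gene Hbb-bt 1300-fold and 1310-fold higher. The red cell list was called higher with the median of each array (0.038 in WT and 0.022 in Keap1 null). In Keap1 null it was also called with quantile normalization (0.049), in the unscaled table (0.019), with normexp (0.02), with symbols only (0.013) and without Keap1 null allograft array 1 (0.041), Keap1 null dish array 1 (0.039) or Keap1 null dish array 2 (0.048). Keratinocyte markers had 4 of 14 higher and 2 lower in each (in WT 4 and 1 over the list alone, in Keap1 null 4 and 2, medians -0.07 and 0.66 with means of 0.22 and 1.02, adjusted p = 0.83 and 0.44). In Keap1 null the keratinocyte median depended on the slide, at 1.54 on slide 1 and 0.03 on slide 2.

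**Figure D3:**
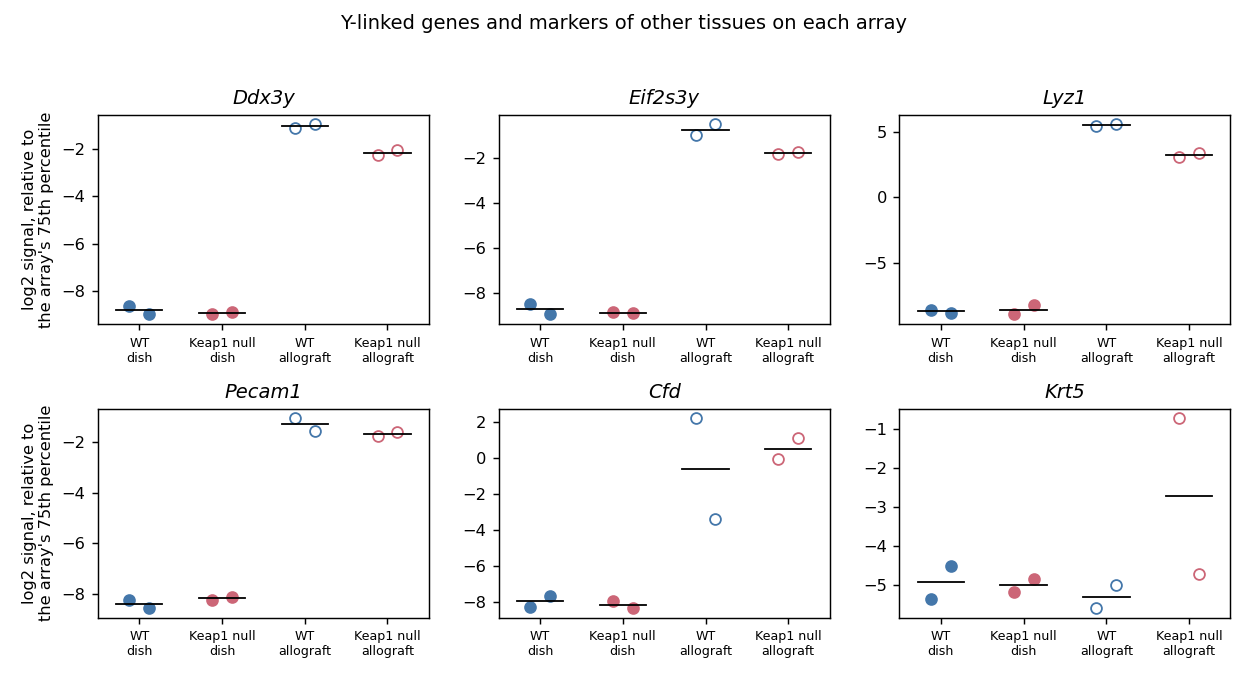
Log2 signal relative to the 75th percentile of each array (vertical axis) for Y-linked Ddx3y and Eif2s3y, the lysozyme gene Lyz1, the endothelial gene Pecam1, the adipocyte gene Cfd and the keratinocyte gene Krt5; each point is an array, filled for dish and open for allograft, and the line is the mean of the group. Cfd was 2.21 and -3.40 on the WT allograft arrays and Krt5 was -0.71 and -4.70 on the Keap1 null allograft arrays, whereas Lyz1 and Pecam1 were close between arrays of a group.

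Matrix and inflammatory genes rose in allografts of both lines. Of 27 extracellular matrix genes, 25 rose and 1 fell in WT and 20 rose and 2 fell in Keap1 null (the same over the list alone), with Postn 1820-fold and 81.1-fold higher. Lumican (Lum) was 267-fold higher in Keap1 null and at least 1650-fold in WT. Matrix genes had medians of 2.71 and 1.96 (camera adjusted p = 4e-08 and 5.9e-05, and adjusted p = 0.12 and 0.17 with an estimated correlation). Pericyte and fibroblast markers rose, 13 of 17 against 1 in WT and 15 against 2 in Keap1 null (the same over the list alone), with Fap at least 88.4-fold and 54.7-fold higher. Pericyte and fibroblast markers had medians of 4.97 and 2.63 (camera adjusted p = 6e-06 and 6.4e-05, and adjusted p = 0.12 in each with an estimated correlation). Matrix proteases rose, 12 of 19 against 3 and 16 against 1 (the same over the list alone), with Mmp9 167-fold higher in Keap1 null and at least 132-fold in WT. Matrix proteases had medians of 1.48 and 1.68 (camera adjusted p = 0.0067 and 6.4e-05, and adjusted p = 0.12 and 0.087 with an estimated correlation). Cytokines and chemokines rose, 16 of 22 against 3 and 15 against 6 (the same over the list alone), with Il1b at least 188-fold and 77.5-fold higher, and Il6 127-fold higher in Keap1 null. Cytokines had medians of 1.80 and 2.65 (camera adjusted p = 0.0027 and 0.022, and adjusted p = 0.12 and 0.21 with an estimated correlation). Interferon response genes rose, 27 of 30 against 1 in WT and 18 against 4 in Keap1 null (27 and 1, and 19 and 4, over the list alone), with Oas2 at least 182-fold and 29.6-fold higher. Interferon genes had medians of 2.97 and 1.30 (camera adjusted p = 4e-08 and 0.0047, and adjusted p = 0.23 and 0.47 with an estimated correlation).

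Cell cycle and cholesterol synthesis genes were lower in allografts of both lines. Allografts also hold host RNA, and all named genes together had medians of -0.21 in WT and -0.17 in Keap1 null. Whether the 2 lists fell within the injected cells themselves was not tested. Of 30 cell cycle genes, 28 fell in WT and 24 fell and 1 rose in Keap1 null (28, and 25 and 1, over the list alone), such as Ccnb1, 2.85-fold lower in WT, and Cdc6, 2.37-fold lower in Keap1 null. Cell cycle genes had medians of -0.79 and -0.45 (camera adjusted p = 3.8e-07 and 6.4e-05, and adjusted p = 0.10 and 0.087 with an estimated correlation). The Keap1 null call ended with quantile normalization (0.054). Cholesterol synthesis genes fell, 23 of 24 in WT and 19 against 1 in Keap1 null (24, and 19 and 1, over the list alone), with Lss 4.67-fold and 3.44-fold lower. Cholesterol genes had medians of -1.30 and -0.83 (camera adjusted p = 4.7e-08 and 5.9e-05, and adjusted p = 0.12 and 0.19 with an estimated correlation).

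Other metabolic and stress genes fell in WT allografts, and camera called none of their lists in Keap1 null. With quantile normalization it called 3 of them higher in Keap1 null: ATF4 targets (0.015), hypoxia (0.0029) and immediate early genes (0.015). The same setting ended the WT calls of hypoxia (0.46, median -0.22) and immediate early genes (0.32, median -0.33). With symbols only, and among probes well above background on all arrays, hypoxia (0.0078 and 0.012) and immediate early genes (0.015 and 0.02) were called higher in Keap1 null, and neither was called in WT (0.18 and 0.22 for each). ATF4 and serine synthesis genes fell in WT, 20 of 23 against 1 (21 and 1 over the list alone), with Chac1 16.9-fold and Asns, asparagine synthetase, 5.38-fold lower. ATF4 targets had a median of -1.49 (camera adjusted p = 8.5e-07, and adjusted p = 0.12 with an estimated correlation). In Keap1 null 8 rose and 5 fell (the same over the list alone, median 0.18, adjusted p = 0.38). Pentose phosphate and NADPH genes fell in WT, 10 of 13 against 1 (the same over the list alone), with Mthfd2 4.24-fold lower, against 4 lower and 1 higher in Keap1 null (the same over the list alone, median -0.10, adjusted p = 0.28). Pentose phosphate genes had a median of -0.94 (camera adjusted p = 0.0027, and adjusted p = 0.12 with an estimated correlation). Heat shock genes fell in WT, 17 of 21 (17 over the list alone), with Hspb1 5.66-fold lower, against 8 lower and 2 higher in Keap1 null (the same over the list alone, median -0.02, adjusted p = 0.12). Heat shock genes had a median of -0.72 (camera adjusted p = 2.6e-05, and adjusted p = 0.12 with an estimated correlation, and 0.052 with quantile normalization). Hypoxia genes were lower in WT (15 of 31 against 7, the same over the list alone), with Eno1 2.82-fold lower, and had 15 higher and 2 lower in Keap1 null (the same over the list alone, median 0.47, adjusted p = 0.11). Hypoxia genes had a median of -0.58 (camera adjusted p = 0.03, and adjusted p = 0.49 with an estimated correlation, and 0.061 with the replicate block). Immediate early genes were lower in WT (13 of 21 against 5, the same over the list alone), with Atf3 3.88-fold lower though Fos was 12.4-fold higher, and had 10 higher and 5 lower in Keap1 null (the same over the list alone, median 1.00, adjusted p = 0.14). Immediate early genes had a median of -0.73 (camera adjusted p = 0.038, and adjusted p = 0.12 with an estimated correlation, and 0.061 with the replicate block).

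In Keap1 null allografts, by contrast, NRF2 targets rose further and p53 targets fell. Of 45 NRF2 targets, 26 rose and 4 fell (26 and 5 over the list alone), with Gpx2 11.5-fold and Slc7a11 7.28-fold higher. NRF2 targets had a median of 0.54 (camera adjusted p = 0.0091, and adjusted p = 0.17 with an estimated correlation). With the median of each array their median was -0.33 and the call ended (0.18). In WT 12 rose and 23 fell (the same over the list alone, median -0.34 with a mean of 0.17, adjusted p = 0.055, and called lower without WT allograft array 2, 0.048, or WT dish array 2, 0.047, with the mean of probes, 0.037, and in the unscaled table, 0.044 with a median of 0.04), although Mgst1 was 177-fold higher. Of 20 p53 targets, 14 fell and 2 rose in Keap1 null (15 and 2 over the list alone), with Ccng1 3.83-fold lower. p53 targets had a median of -0.59 (camera adjusted p = 0.0017, and adjusted p = 0.17 with an estimated correlation). In WT 12 rose and 4 fell (the same over the list alone, median 0.47, adjusted p = 0.082), with Fas 18.4-fold higher. The p53 list was called higher in WT with quantile normalization (0.00073), normexp (0.0079), symbols only (0.011) and no filter on dim probes (0.018), and among probes well above background on all arrays (0.007). Hox and limb genes fell in Keap1 null, 15 of 28 against 8 (the same over the list alone), with Hoxb2 7.05-fold lower. Hoxb13, which is not in the list, was at least 31.3-fold lower. Among the tested members of the list the clusters differed: 6 of 6 HoxB genes fell, HoxA genes went both ways (4 of 9 higher and 4 lower), and 4 of 5 HoxD genes rose. Hox and limb genes had a median of -0.97 (camera adjusted p = 0.02, and adjusted p = 0.15 with an estimated correlation, and 0.14 with the median of each array). In WT 12 rose and 6 fell (the same over the list alone, median 0.16, adjusted p = 0.30). Contractile genes were called in neither line (6 of 13 rose and 3 fell in WT, 3 rose and 6 fell in Keap1 null, the same over the list alone, medians 0.31 and -0.29 with means of 1.10 and 0.04, adjusted p = 0.46 and 0.22).

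Among the largest fitted falls in WT allografts were those of Lce1g (81.2-fold, well above background on 1 of 2 allograft arrays) and Lce1i (at least 35.8-fold), genes of the skin's cornified layer, Anxa10 (49.8-fold), Atp13a4 (at least 13.0-fold) and Cyp1a1, a cytochrome P450 (at least 11.2-fold). In Keap1 null they included Vat1l (87.7-fold, well above background on 1 of 2 allograft arrays), Hoxb13, Cyp1a1 (at least 26.2-fold), Hhip, an antagonist of hedgehog signals (61.1-fold), and Bex2 (61.0-fold). Keap1 was 1.42-fold lower in WT allografts than in dishes (adjusted p = 0.0423) and 2.53-fold lower in Keap1 null (adjusted p = 0.000935). The WT call ended with quantile normalization (limma adjusted p = 0.721), in the unscaled table (0.69), with only the arrays compared (0.101) and with no filter on dim probes (0.0606). The WT log2 fold change was -0.50, against -0.12 in the unscaled table, -0.31 without WT allograft array 2 and -1.53 with the median of each array.

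Between allograft and dish, 15599 targets were called in WT, 8217 higher and 7382 lower, and 14874 in Keap1 null, 8207 higher and 6667 lower. At least 2-fold changes numbered 8772 and 8134. Shared were 6195 higher and 4712 lower calls, where independent lists would share 2942 and 2147 (odds ratios 19.3 and 12.3), and 612 and 613 were called in opposite directions; across all targets, r = 0.781. The called targets with a symbol leaned lower, with 4098 higher and 5951 lower in WT and 4007 higher and 5474 lower in Keap1 null. The direction of single calls leans on the scaling. In WT 52.7% of calls were higher, against 25.9% with the median of each array and 78.5% in the unscaled table, and the median over all targets was -0.02, against -1.04 and 0.36. In Keap1 null 55.2% were higher, against 27.3% with the median of each array and 44.5% with quantile normalization, and the median over all targets was 0.03, against -0.84 and -0.16. List calls changed with the scaling too. With the median of each array, heat shock (adjusted p = 0.015) and pentose phosphate genes (0.033) were called lower in Keap1 null, and immediate early genes in WT were not called (0.11). Adipocyte markers were called higher in WT and Keap1 null with that scaling (0.0074 and 0.0027), with symbols only (0.025 and 0.0086), with no filter on dim probes (0.034 and 0.038) and without WT allograft array 2 (0.0026 and 0.0041). In Keap1 null they were also called in the unscaled table (0.029), with only the arrays compared (0.0058) and without WT allograft array 1 (0.0037).

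The interaction asks whether the genotype difference itself differs between allograft and dish. It did for 7529 targets, 3630 with a more positive and 3899 with a more negative difference in allografts. Of these, 735 were higher in Keap1 null dishes and lower in Keap1 null allografts, 448 the reverse, and 2057 each were called only in allografts as higher or as lower. ATF4 and serine synthesis genes had the clearest turn, with 20 of 23 more positive in allografts and none more negative (22 and 0 over the list alone), among them Chac1 (log2 difference 4.39), Slc7a11 (4.10) and Trib3 (3.18). ATF4 targets had a median difference of 1.79 (camera adjusted p = 1.7e-11, and adjusted p = 0.12 with an estimated correlation). NRF2 targets were more positive, 27 of 45 against 8 (27 and 9 over the list alone), but Mgst1 was more negative (-5.82). NRF2 targets had a median of 1.00 (camera adjusted p = 0.00023, and adjusted p = 0.12 with an estimated correlation).

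Hypoxia genes were more positive (18 of 31 against 4, 21 and 5 over the list alone), such as Stc2 (3.50). Hypoxia genes had a median of 1.00 (camera adjusted p = 0.00013, and adjusted p = 0.30 with an estimated correlation). Of 21 immediate early genes 12 were more positive and 2 more negative (the same over the list alone), such as Nr4a1 (5.04). Immediate early genes had a median of 0.98 (camera adjusted p = 0.001, and adjusted p = 0.12 with an estimated correlation). Of 21 heat shock genes 12 were more positive and 1 more negative (13 and 1 over the list alone), such as Hsph1 (1.87). Heat shock genes had a median of 0.63 (camera adjusted p = 0.00013, and adjusted p = 0.14 with an estimated correlation). Of 24 cholesterol synthesis genes 10 were more positive and 1 more negative (12 and 1 over the list alone). Cholesterol genes had a median of 0.46 (camera adjusted p = 0.0017, and adjusted p = 0.28 with an estimated correlation). Of 13 pentose phosphate and NADPH genes 6 were more positive (6 and 1 more negative over the list alone), such as Mthfd2 (2.27). Pentose phosphate genes had a median of 0.45 (camera adjusted p = 0.021, and adjusted p = 0.14 with an estimated correlation). Of 30 cell cycle genes 9 were more positive (9 over the list alone), such as Ccnb1 (1.30). Cell cycle genes had a median of 0.31 (camera adjusted p = 0.0055, and adjusted p = 0.14 with an estimated correlation). The cell cycle call ended with quantile normalization (0.37) and in the unscaled table (0.11, where the median was -0.05), and the pentose phosphate call ended in that table (0.059) and with normexp (0.077).

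Interferon response genes went the other way, 26 of 30 more negative in allografts (27 over the list alone), such as Gbp2 (-4.33). Interferon genes had a median of -1.84 (camera adjusted p = 2.1e-10, and adjusted p = 0.22 with an estimated correlation). Of 20 p53 targets 12 were more negative (13 over the list alone), such as Fas (-4.30). p53 targets had a median of -0.96 (camera adjusted p = 4.6e-06, and adjusted p = 0.12 with an estimated correlation). Of 24 macrophage markers 16 were more negative and 1 more positive (19 and 2 over the list alone). Macrophage markers had a median of -2.20 (camera adjusted p = 9.4e-07, and adjusted p = 0.12 with an estimated correlation). Of 10 MHC class II genes 8 were more negative and 1 more positive (the same over the list alone), such as Cd74 (-3.20). MHC class II genes had a median of -2.12 (camera adjusted p = 0.00067, and adjusted p = 0.12 with an estimated correlation). Of 20 lymphocyte markers 10 were more negative (10 over the list alone). Lymphocyte markers had a median of -1.46 (camera adjusted p = 0.00022, and adjusted p = 0.22 with an estimated correlation). Of the macrophage and lymphocyte markers, 16 and 13 were dim in dishes, so these differences largely repeat those between the allografts. Among probes well above background on all arrays the MHC class II call ended (0.085, median -2.10), as did the lymphocyte call (0.47, median 0.01).

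Genes of connective tissue and body position were more negative as well. Of 27 extracellular matrix genes 14 were more negative and 3 more positive (17 and 3 over the list alone), such as Bgn, which encodes biglycan (-4.73). Matrix genes had a median of -0.91 (camera adjusted p = 0.00017, and adjusted p = 0.21 with an estimated correlation). Of 13 contractile genes 6 were more negative (7 over the list alone), such as Myl9 (-5.97). Contractile genes had a median of -1.02 (camera adjusted p = 0.0059, and adjusted p = 0.14 with an estimated correlation). Of 17 pericyte and fibroblast markers 9 were more negative and 2 more positive (the same over the list alone), such as Pdgfrb (-3.68). Pericyte and fibroblast markers had a median of -1.49 (camera adjusted p = 0.014, and adjusted p = 0.22 with an estimated correlation). Of 28 Hox and limb genes 15 were more negative and 3 more positive (15 and 4 over the list alone), such as Hoxb5 (-3.31). Hox and limb genes had a median of -1.16 (camera adjusted p = 2.8e-05, and adjusted p = 0.12 with an estimated correlation).

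Lists without a call in the interaction included matrix proteases (6 of 19 more positive and 7 more negative, 7 and 8 over the list alone, median -0.09 though the test pointed up, adjusted p = 0.89) and cytokines (6 of 22 and 10, 6 and 11 over the list alone, median -1.17, adjusted p = 0.16). Neutrophil markers (4 of 13 and 2, median 0.66, adjusted p = 0.23), endothelial markers (1 of 22 and 3, median -0.21, adjusted p = 0.32), adipocyte markers (1 of 13 and 0, median 0.73, adjusted p = 0.26), keratinocyte markers (1 of 14 and 2, median 0.64, adjusted p = 0.67), red cell markers (0 of 5, median 0.20, adjusted p = 0.35) and sex-linked markers (0 of 4 and 1, median -0.52, adjusted p = 0.32) had the same counts over the list alone. Skeletal muscle markers had 3 of 15 more positive (3 over the list alone, median 1.35, adjusted p = 0.054, and called with the replicate block, 0.036, quantile normalization, 0.029, normexp, 0.031, and in the unscaled table, 0.0013). On slides 1 and 2 the adipocyte medians were -0.38 and 1.19 and the keratinocyte medians 1.30 and 0.29, so both depended on single arrays. The largest fitted positive differences were in Spink6, Tac1, Atp13a4, Dipk1c and Gldn, and the largest fitted negative ones in Ogn, Nrep, Dlk1, Xlr4b and Xlr3c. Of these, Tac1, Dlk1 and Xlr4b were well above background on all arrays, and the size for the others rests on a dim group. Keap1 (-0.83, adjusted p = 0.0475) and Nfe2l2 (0.54, adjusted p = 0.0356) passed the test narrowly, and with no filter on dim probes neither did (0.0777 and 0.0718). Nfe2l2 did not pass without any 1 of the 8 arrays (lowest adjusted p = 0.0508), with quantile normalization (0.28, adjusted p = 0.228) or in the unscaled table (0.18, adjusted p = 0.741). Keap1 did not pass in 6 of the 8 fits without an array or with the median of each array (-0.68, adjusted p = 0.15). Of the interaction calls 48.2% were more positive, against 23.3% in the unscaled table, and the median over all targets was 0.04, against -0.31. At least 2-fold differences numbered 4688.

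**Figure D4:**
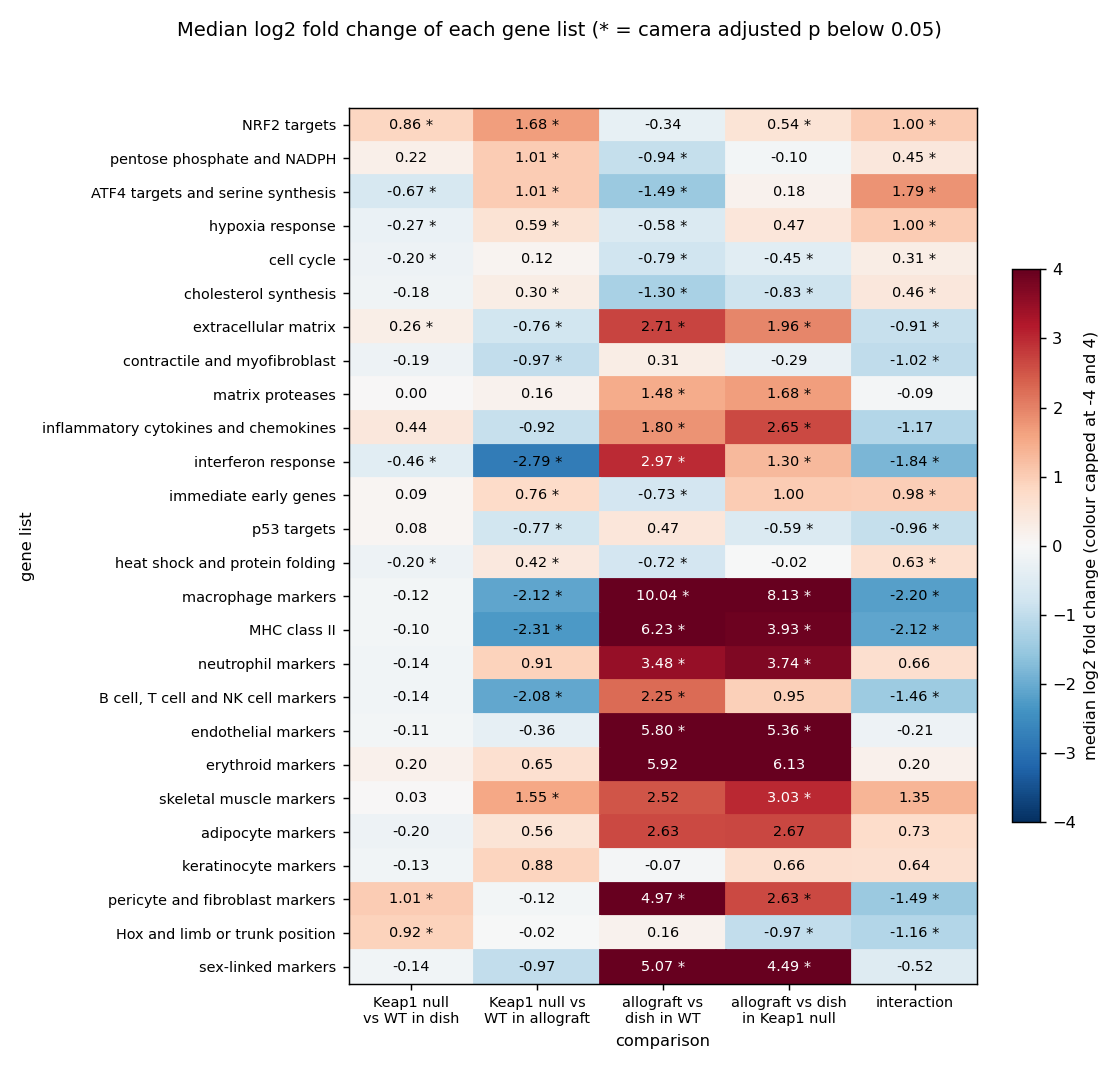
Median log2 fold change of each of the 26 gene lists (rows) in the 5 comparisons (columns), with the colour capped at -4 and 4 and an asterisk where the camera adjusted p was below 0.05. Macrophage markers had the largest medians, 10.04 and 8.13 between allograft and dish, and ATF4 targets changed sign between the genotype columns, from -0.67 to 1.01.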

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

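The interaction was planned, with its lists and the rule that names its genes, and the tests of explanations below, with the counts of Hox clusters and clones, were chosen only after the results had been seen. The genotype effect differed between allograft and dish for 7529 targets, and 17 lists differed with them, of which 0 stayed called with an estimated correlation. Median differences of the genotype effect were 1.79 for ATF4 targets, 1.00 for NRF2 targets, 1.00 for hypoxia, 0.98 for immediate early genes, 0.63 for heat shock, 0.46 for cholesterol synthesis, 0.45 for pentose phosphate and NADPH and 0.31 for the cell cycle. They were -2.20 for macrophage markers, -2.12 for MHC class II, -1.84 for interferon response, -1.49 for pericytes and fibroblasts, -1.46 for lymphocytes, -1.16 for Hox and limb genes, -1.02 for contractile genes, -0.96 for p53 targets and -0.91 for matrix. The largest fitted gene differences were Spink6 (9.70), Tac1 (9.46), Atp13a4 (8.77), Dipk1c (7.80) and Gldn (7.61), and on the other side Ogn (-8.67), Nrep (-7.94), Dlk1 (-7.89), Xlr4b (-7.57) and Xlr3c (-7.48). For macrophage and lymphocyte markers, mostly dim in dishes, the values largely repeat the difference between allografts. For the genes other than Tac1, Dlk1 and Xlr4b, at least 1 group was not well above background, so their exact sizes and order are not known. Keap1 differed by -0.83 and Nfe2l2 by 0.54.

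Leukocyte and interferon genes were lower in Keap1 null allografts, which could reflect a smaller share of host cells. The macrophage median fell below the endothelial median by a difference of -1.76 (-2.12 against -0.36, permutation p = 0.00028). This p measures spread over non-independent genes, not tumours. The medians were -2.13 against -0.37 on slide 1 and -2.14 against -0.25 on slide 2. On these arrays this argues against an equal fall of all host cells as the whole cause. Ddx3y (-1.13) and Eif2s3y (-1.03) fell, but the muscle median was 1.55, leaving a lower host share open. The interferon median lay below the macrophage median by a difference of -0.67 (-2.79 against -2.12, permutation p = 0.015 over genes). That permutation ignores the correlation of 0.464 estimated in the interferon list. Fewer leukocytes also need not lower both lists equally, so the test leaves them open as the whole cause. Host leukocytes cannot explain the dish interferon median of -0.46 (camera adjusted p = 7.9e-05, 0.75 with an estimated correlation). Injected cell number, with 0 genotypes at more than 1, cannot be told apart from genotype.

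Among the tested members of the Hox list, in Keap1 null allografts 6 of 6 HoxB genes fell (median -2.69), HoxA genes went both ways (4 of 9 higher and 4 lower, median -0.64) and 4 of 5 HoxD genes rose (median 1.84). Dilution of tumour RNA by host RNA might lower some of them, and the HoxB median lay below the HoxA median by a difference of -2.05 (exact permutation p = 0.029 over 5005 splits), but the clusters were compared because they were seen to part, so this leaves dilution open. A different body position of origin of the lines is another reading: of 22 Hox and limb genes called between the genotypes in dishes, 17 were called in the same direction in allografts and 4 in the opposite one. With 1 line per genotype, position of origin and loss of Keap1 cannot be told apart.

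Of 4432 tested cDNA clones without a gene symbol, 2945 rose and 445 fell in WT allografts and 2999 rose and 401 fell in Keap1 null allografts. Their medians were 1.66 and 1.71, against -0.21 and -0.17 for named genes, and over all 8638 clone probes, before the filter on dim probes, 0.17 and 0.42, against -0.30 and -0.08 for other probes with a symbol. Genomic DNA or raised background in tumour RNA could lift all dim probes. Unfiltered, 1064 olfactory, vomeronasal and trace amine receptor probes had medians of -0.46 and 0.04. They differed from the 8638 clone probes by -0.63 in WT and -0.38 in Keap1 null (permutation p = 1e-05 over probes, the minimum). At most 21.3% of them were well above background per group, so this tests it weakly. Scaling could also lift dim probes. The tested clones stayed above named genes of the same brightness by 1.11 and 1.41, in 10 of 10 bins, a gap that no scaling factor can make or remove. The rise itself does move: with the median of each array, the median over all targets was -1.04 in WT and -0.84 in Keap1 null. A rise in allografts also helps a clone pass the filter. Scaling thus stays open for the rise, though a factor per array does not account for the gap. Transcripts of host cells could also be the cause, and the clones that rose in WT had a median of 0.06 in Keap1 null against WT allografts, which lies between -1.03 for Y-linked genes and 1.55 for muscle markers, so host cells cannot be excluded.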

How the results depend on the processing

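Normexp on the median signal, the test of targets with symbols only, and the replicate block with an estimated correlation were chosen after seeing the data. Of the results compared, 128 stayed the same and 31 moved. A result here is a count of calls, and the same means a count of similar size, whatever its genes or directions. With the median of each array, 909 targets in WT growth and 589 in Keap1 null growth were called opposite to the main fit. With quantile normalization these numbered 209 and 81. Requiring a 2-fold change left 1899 and 4545 calls between genotypes in dishes and allografts, 8772 and 8134 between allograft and dish in WT and Keap1 null, 4688 in the interaction, and 764 and 5571 shared calls. A stricter adjusted p left 2450, 6209 and 4237 (dishes, allografts, interaction) and 1020 shared genotype calls. In dishes the unscaled table gave 2620 genes, 5 lists and 1010 shared calls, and normexp on the median signal gave 2857 and 1214. With only the arrays compared, 1330 genotype calls were shared. With symbols only, 10243 and 9704 targets were called between allograft and dish, and 6777 shared. Estimated correlation left list calls of 1, 0, 0, 0 and 0, the replicate block with it 0 in all 5, and fry called 25 lists in Keap1 null growth. Leaving out single arrays gave 2310 to 4389 calls in dishes and 1074 to 1693 shared genotype calls, both lowest without Keap1 null dish array 1. With the replicate block, 6517 targets were called in dishes, 11418 in allografts, 17070 in WT growth, 16486 in Keap1 null growth and 9379 in the interaction. The replicate block changed no list call beyond those given. Normexp on mean signals, planned, was not run. The cause of these changes was not tested.

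Some log2 fold changes reversed sign. Xist in dishes was 0.09 (quantile), 0.13 (unscaled), 0.01 (mean of probes), 0.05 (normexp), 0.08 without Keap1 null dish array 2 and 0.07 without WT dish array 2. Nfe2l2 in WT growth was 0.44 (quantile), 0.38 (unscaled), 0.02 (normexp), 0.06 without WT dish array 2 (-0.08 without array 1) and 0.05 without WT allograft array 1. In dishes Nfe2l2 was -0.09 (median) and -0.01 without WT dish array 1 (0.14 without WT dish array 2), and in Keap1 null growth -0.34 (median). With the median of each array, Xist was -0.27 and Cyp1b1 -0.78 in WT growth, and H6pd -0.21 and Perp -0.12 in Keap1 null growth. Cyp1b1 in WT growth was -0.24 (quantile), Ahrr 0.31 (unscaled), Mylk in dishes 0.28 (mean of probes), and Eif2s3y in dishes 0.08 without WT dish array 1 and -0.39 without array 2.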

Other observations

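The genes named here, and the tests on them, were chosen only after the values had been seen. The following single genes were higher in Keap1 null than in WT allografts, and no list of their kind was tested. The peptide hormone gene Cck was 186-fold higher (adjusted p = 1.11e-05), and Pcsk1, which encodes an enzyme that cuts peptide hormones from their precursors, at least 38.3-fold (1.16e-05). Akr1c18, which inactivates progesterone, was 74-fold higher (1.02e-05), Tnfsf11, the osteoclast factor RANKL, 41.2-fold (9.38e-06), and the EGF receptor ligand Ereg 26.2-fold (8.11e-05).

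For 6 imprinted or clustered genes the genotype difference had opposite signs in the growth conditions; other genes of that kind were not counted. In Keap1 null dishes Dlk1 was 52.7-fold, Meg3 31-fold, Mest 29.3-fold, Xlr4b 96.1-fold and Igf2 at least 7.8-fold higher than in WT, and Rian was 43.8-fold higher with 1 of 2 WT arrays well above background. In Keap1 null allografts the same genes were lower than in WT: Dlk1 4.5-fold, Meg3 2.8-fold, Rian 2.43-fold, Mest 1.89-fold, Igf2 7.14-fold and Xlr4b 1.98-fold. Between genotypes in dishes, the median log2 fold change was 1.63 over the HoxA genes of the list, -0.97 over its HoxB, 0.40 over its HoxC and 5.13 over its HoxD genes, and in allografts 1.37, -3.60, -1.29 and 2.44.

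The fall of Cyp1a1 in allografts of both lines could reflect less activity of the aryl hydrocarbon receptor. Of its other targets Cyp1b1, Ahrr and Tiparp, 1 (Tiparp, 1.64-fold in WT and 1.79-fold in Keap1 null) was lower in both lines, and Cyp1b1 (18-fold) and Ahrr (4.23-fold) were lower in Keap1 null. The count was 1 with quantile normalization, 0 in the unscaled table and 3 with the median of each array, where Cyp1b1 was -0.78 in WT. With that last scaling 14296 of 19300 called targets were lower in WT, so the falls do not single out the receptor, and the reading stays open. A measurement of receptor ligands in the culture serum would separate the readings.

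Y-linked transcripts may come from male host cells. Of 3 Y-linked genes tested, 2, Ddx3y and Eif2s3y, were well above background on all 4 allograft arrays and on none of 4 dish arrays, which is consistent with host RNA in the tumours. The other, Kdm5d, was well above background on all 4 allograft arrays, higher there in both lines (2.36 and 2.20), but also on 1 of 2 dish arrays of each line, so some Y-linked signal in the lines is not excluded. Xist, which male cells do not express, was higher in allografts of both lines (0.75 and 0.89), although male host RNA alone would lower it, and with the median of each array it was -0.27 in WT. Among its other probes the values were 0.91 and 1.12, 1.05 and 1.08, and 0.31 and 0.21, the last without a call in either line. A record of the sex of the mice and of the embryos would decide it. The adipocyte genes differed between the WT allograft arrays by a median absolute log2 difference of 1.12, against 0.37 and 0.21 between the dish arrays of WT and Keap1 null and 0.57 between Keap1 null allograft arrays. Muscle genes differed by 1.49 and 1.79 in the allografts and keratinocyte genes by 1.81 in Keap1 null, while macrophage genes differed by 0.18 and 0.08 and endothelial genes by 0.16 and 0.17. Arrays of a group could be from separate tumours taken with different amounts of adjacent tissue, but these values restate the difference that raised the question, on 1 pair of arrays per group, so this stays open, and histology of the same pieces would test it.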
